A study of Homo sapiens with 62 samples.

How the data were processed

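Stranded mRNA libraries (KAPA kit, per the labels) were sequenced from SUM-229PE cells, their resistant derivatives and 2 other triple-negative lines, 62 samples in all. The authors aligned the reads to hg19 (GRCh37) and quantified genes with RSEM and SAMtools, per the submitters' processing notes, which give no versions. Each file lists 20531 genes. The 29 unnamed ones hold 0.0457% of all values (0.132% in the library with most) and were left out, which leaves 20502 named genes. In 38 files (chronic series, HCC1806, SUM159, sorted and isolated cells) the deposited values are RSEM expected counts without rescaling, per the file headers, or for HCC1806 library 3 from its identity with library 1. In the other 24 files (DMSO, 30 nM and resistant libraries of SUM-229PE) the deposited values are signal values, RSEM counts that the authors rescaled within each library so that the 75th percentile of genes above 0 is near 1000. That rescaling was read from the values, since no header states it. Between 87.9% and 90.2% of their low values lie within 0.02 of a whole multiple of 1 step per library. This is too few to recover whole reads, so no count test was run on them.

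Groups follow the labels. Titles number the 30 nM libraries 1 to 3 and descriptions 4 to 6, and the descriptions were used, so that these libraries were set against DMSO libraries 4 to 6. The resistant lines were set against POS DMSO libraries 1 to 3. POSR1 and POSR2 were selected for 6 weeks at 10 nM and then kept at 30 nM, per the labels. All cells were at passage 15 to 18, or 15 to 19 for 2 libraries, per the labels. HCC1806 library 3 repeats library 1 and was counted once. The 8 single libraries of sorted and isolated cells were described without a test.

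Expected counts were rounded and tested with edgeR 4.0.16 (quasi-likelihood test, TMM factors, edgeR's filter on low counts) in R 4.3.3. The design had assumed counts for every file, so the signal files were moved to limma 3.58.1 (mean-variance trend) on log2(value + 1), for genes at 10 or more in at least 3 libraries. All groups of a series shared 1 fit, and p-values were adjusted over all genes tested by Benjamini-Hochberg with a threshold of 0.05. The acute and chronic differences are interaction terms, the POS change minus the NEG change. For a group listed at 0 in all its expected count libraries, the fold is a lower bound against 3 counts over the group. Medians of gene lists use the fitted changes unless stated.

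The 19 gene lists, the comparisons, the tests and the rule for naming genes were fixed before the data were examined. They are ERK output, receptor tyrosine kinases, cell cycle, sort gate genes, basal epithelial, luminal epithelial, epithelial junction, mesenchymal, interferon-stimulated, MHC, inflammatory cytokine, AP-2 and lineage factors, transcription elongation and enhancer, cholesterol synthesis, lysosome and autophagy, apoptosis regulators, immediate early and heat shock, other cell types, and replication-dependent histones. ELF5, GRHL2 and TP63 are in more than 1 list, and NELFE is not in the files. Lists were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted within each comparison, and again with the correlation estimated from the data. POS-high and NEG-high lists hold the 200 genes with the largest baseline difference, from libraries outside the comparison tested. In the sorted and isolated cells, a list's median log2 ratio was placed among 10000 random lists of equal size and level. Genes named are the 12 largest rises and the 12 largest falls among called genes whose libraries do not overlap and whose higher group reaches the median level, and members of the fixed lists.

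Each kind of test was tested on simulated data with 200 changed genes, drawn at the levels of 1 control group and the spread of the real libraries. POS and NEG cells thus had no baseline difference in the simulated data. The changed genes were taken from those above a minimum level, so the shares recovered do not cover scarce genes. Genes were drawn independently, so the list check does not cover lists whose genes are correlated. For acute POS, 96% of genes changed 1.5-fold and 100% of those changed 2-fold were recovered over 12894 genes, with 14 unchanged genes called. For the acute difference (12890 genes) the shares were 80% and 100%, with 17 unchanged genes called, and for POSR1 (12994 genes) 92% and 100%, with 18. For chronic POS day 35 (13704 genes) they were 94% and 100%, with 9 unchanged genes called, and for the chronic difference at day 35 (13696 genes) 76% and 88%, with 11. For HCC1806 against SUM159 (13464 genes), 10% of genes changed 4-fold and 64% of those changed 16-fold were recovered, so that comparison misses most smaller changes. In each case the lowered cell cycle list was called, and 1 unchanged list, the 2 sort gate genes in the chronic difference at day 35, was called as well. Precision follows the depths given with the data, and intervals for counting error were not added because spread between libraries enters every test.

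Alternatives tried were DESeq2 1.42.0, RLE size factors, limma on the expected counts, no filter on low values, upper-quartile rescaling, pseudocounts of 0.25 and 10, a replicate block, only the groups compared, other DMSO sets, and each library left out. TMM rescaling of the signal values, HCC1806 library 3 counted, a block in the list tests and estimated correlation for the POS-high and NEG-high lists were added after the values had been seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.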

Results

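SUM-229PE, a triple-negative breast cancer line from a pleural effusion per the labels, holds 2 subpopulations that were separated by flow cytometry. POS cells carry EpCAM and CD49f, and NEG cells carry neither. The 62 libraries cover the response of POS and NEG cells to the MEK inhibitor trametinib, at 30 nM for 24 h or at 10 nM over 35 days. They also hold 2 trametinib-resistant POS lines (POSR1 and POSR2), the lines HCC1806 and SUM159 in DMSO, and 8 single libraries of sorted or isolated cells. Expected counts summed to between 16.4 and 36.8 M per library in the chronic series, 22.1 and 27.8 M in the lines and 18.3 and 26.8 M in the sorted and isolated cells. The rescaled signal files imply 7.05 to 16.3 M counts for the resistant lines and DMSO libraries 1 to 3 of POS and NEG cells. For the 30 nM libraries and their DMSO libraries 4 to 6 they imply 30.2 to 34.8 M. The 7.05 M library is NEG DMSO library 3, while the resistant lines and their POS controls start at 11.8 M. Each group compared has 3 libraries, except HCC1806, whose library 3 repeats the values of library 1 and was counted once (n = 2). A gene is called at a Benjamini-Hochberg adjusted p under 0.05, by limma for the acute and resistant groups and by edgeR for the chronic groups and the lines. These p-values measure the spread between these libraries alone. The labels do not say whether the libraries of a group come from separate cultures, so that spread is possibly technical. Counts of list genes that rose or fell are adjusted over the list alone, and they equal those adjusted over all genes tested in 332 of 377 pairs of a fixed list and a comparison, with a difference of at most 5 genes in the others. Counts in the POS-high and NEG-high lists, the 200 genes that differ most at baseline, differ by more in places (134 against 116 POS-high genes higher in HCC1806).

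POS and NEG cells differ as an epithelial and a mesenchymal state. In DMSO, POS cells carried CDH1 at a mean signal of 6559 (SD 75.6) against 7.12 (SD 5.77) in NEG cells, ITGB6 at 15390 against 13.5, LAMA3 at 12270 against 14.5, KRT5 at 32000 against 59.2 and GRHL2 at 1517 against 1.09. NEG cells carried FN1 at 444700 (SD 17430) against 9286 (SD 235) in POS cells, COL6A3 at 125500 against 41.3, BGN at 27880 against 40.5, PDGFRA at 4008 against 1.44 and CXCL12 at 3275 against 1.5. VIM was abundant in both, at 82990 in NEG and 15330 in POS cells. The sort markers followed the labels: EPCAM stood at 2991 in POS and 18.9 in NEG cells, and ITGA6, which encodes CD49f, at 9668 and 117. All 22 epithelial junction genes were higher in POS cells (median log2 difference 5.83, camera adjusted p 2.73e-09). The 14 basal epithelial genes were higher too (median 6.86, adjusted p 3.11e-07, or 0.151 with the correlation between genes estimated from the data), as were 10 of 11 luminal epithelial genes (median 4.79, adjusted p 0.000109, or 0.135). Of 25 mesenchymal genes, 23 were lower in POS cells (median −4.31, adjusted p 7.70e-08). POS cells also carried more of all 17 cholesterol synthesis genes (median 1.12, adjusted p 3.11e-07). They carried less of 16 of 17 MHC genes (median −1.12, adjusted p 3.41e-05, or 0.143 with estimated correlation). limma called 11943 of 13883 genes, 5370 higher and 6573 lower in POS cells (n = 3 and 3).

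The untreated cells of the chronic series repeat the epithelial and mesenchymal contrast on other libraries. At day 0, KRT5 stood at 1175 CPM (expected counts scaled to library size; SD 82.9) in POS against 0.0634 (SD 0.0549) in NEG cells. COL6A3 stood at 12010 CPM in NEG against 1.29 in POS cells, PDGFRA at 410 against 0.0149 and COL1A2 at 248 against 0.0334. The 2 sort gate genes were higher in POS cells (median 6.67, adjusted p 0.00706). The cells were separated on the proteins of these 2 genes, so this is no independent evidence of the contrast. All 22 junction genes were higher in POS cells (median 6.32, adjusted p 3.20e-13) and 22 of 25 mesenchymal genes were lower (median −5.04, adjusted p 1.78e-12). All 19 MHC genes were lower in POS cells (median −1.81, adjusted p 1.41e-08). The interferon-stimulated list varied between untreated libraries. All 22 genes were lower in POS cells at day 0 (median −2.31, adjusted p 6.24e-11, or 0.0505 with estimated correlation), and 16 were lower and 2 higher in DMSO (median −0.67, adjusted p 0.00861, or 0.636). With DMSO libraries 1 to 3 the list was not called (−0.19, adjusted p 0.474), and 13 of 22 were higher in POS cells in both the sorted and the isolated DMSO libraries. Among the AP-2 and lineage factors, 9 of 13 were higher and 2 lower in POS cells (median 1.22, adjusted p 0.00161). The list of other cell types was not called (5 genes measured, median −1.41, adjusted p 0.345). edgeR called 11878 of 14877 genes, 5857 higher and 6021 lower in POS cells (n = 3 and 3).

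In NEG cells, 24 h of 30 nM trametinib lowered ERK output transcripts such as ETV4 and DUSP6 and raised WISP2, H19 and the collagen genes COL1A2 and COL3A1. ETV4 fell from a mean signal of 550 (SD 16.9) to 15.1 (SD 2.32), DUSP6 from 1041 to 42.4, SPRY4 from 530 to 22.2, EGR1 from 2586 to 285 and AREG from 1454 to 107. HMGA2 fell from 8905 to 1056 and NT5E from 8551 to 1098. WISP2 rose from 43.8 to 1938, H19 from 974 to 14660, CDKN1C from 124 to 1305, COL1A2 from 856 to 10350 and COL3A1 from 57.5 to 790. The apoptosis gene BMF rose from 50.7 to 1011. Of 18 ERK output genes, 17 fell (median −1.84, adjusted p 9.60e-09, or 0.115 with estimated correlation). Proliferation genes moved less: 23 of 24 cell cycle genes fell, by a median of 0.65 on the log2 scale (adjusted p 1.07e-10), and MKI67 went from 6599 to 4797. Of 22 interferon-stimulated genes, 20 rose (median 0.95, adjusted p 5.68e-05, or 0.566 with estimated correlation), with IFI6 going from 1948 to 4509. Lysosome and autophagy genes rose in 15 of 18 cases (median 0.46, adjusted p 5.74e-05, or 0.283). limma called 10482 of 13883 genes, 6159 higher and 4323 lower (n = 3 and 3), of which 1172 rose and 510 fell at least 2-fold. With values rescaled by TMM, 5182 were higher and 5202 lower, and with DMSO libraries 1 to 3 as the controls 5200 and 2066, so the excess of rises depends on the scaling and the controls.

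In POS cells, the same exposure lowered ERK output and cell cycle genes by more and raised KRT16 and SERPINB13. DUSP6 fell from a mean signal of 1787 (SD 46.4) to 3.72 (SD 1.45), ETV5 from 1622 to 5.40 and FOSL1 from 466 to 18.6. AURKB fell from 985 to 61.0, RRM2 from 8736 to 491, CCNB1 from 4442 to 514 and LMNB1 from 5377 to 293. KRT16 rose from 141 to 3438, SERPINB13 from 69.8 to 1590, MAF from 44.7 to 1140, OLR1 from 15.2 to 598, FBXO32 from 456 to 9911 and BMF from 65.7 to 1202. Of 18 ERK output genes, 16 fell and 1 rose (median −3.19, adjusted p 5.41e-07, or 0.25 with estimated correlation). EGR1, one of them, was not called (557 at 30 nM, log2 change 0.04, adjusted p 0.697 by limma). All 24 cell cycle genes fell (median −3.12, adjusted p 6.19e-17). Basal epithelial genes rose in 13 of 14 cases (median 1.44, adjusted p 0.00290, or 0.348 with estimated correlation) and luminal epithelial genes in 9 of 11 (median 1.12, adjusted p 0.0269, or 0.348). Of 18 lysosome and autophagy genes, 16 rose (median 0.73, adjusted p 2.44e-05, or 0.276). limma called 11133 of 13883 genes, 6087 higher and 5046 lower (n = 3 and 3), of which 1517 rose and 1361 fell at least 2-fold.

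The POS response exceeded the NEG response for proliferation and for ERK output. With the difference taken as the POS change minus the NEG change, all 24 cell cycle genes had a lower change in POS cells (median −2.67, adjusted p 1.25e-19). LMNB1, which is not in that list, stood at −3.49. Of 18 ERK output genes, 15 had a lower change (median −1.47, adjusted p 0.00131, or 0.504 with estimated correlation), among them ETV5 (−4.88) and DUSP6 (−4.02). EGR1 differed the other way (3.22). IGFBP3 rose in POS cells from 4067 to 41980 and KRT13 from 2008 to 18220, with differences of 3.75 and 3.97, while H19 rose more in NEG cells (−3.63). limma called 8870 of 13883 genes, 3757 with a higher and 5113 with a lower change in POS cells. This split rests on the scaling: with values rescaled by TMM, 5454 had a higher and 3608 a lower change in POS cells among 9062 called, and the median of all genes moved from −0.07 to 0.08. With DMSO libraries 1 to 3 as the controls, the number called was 4699, and with all 6 DMSO libraries 4820. The single sorted and isolated libraries at 30 nM, which were not tested, kept the order with smaller gaps. Their cell cycle medians were −1.08 in POS and −0.63 in NEG sorted cells, and −1.83 and −1.32 in isolated cells. Their ERK output medians were −2.75 and −1.93 in sorted cells, and −2.26 and −2.00 in isolated cells.

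**Figure D1:**
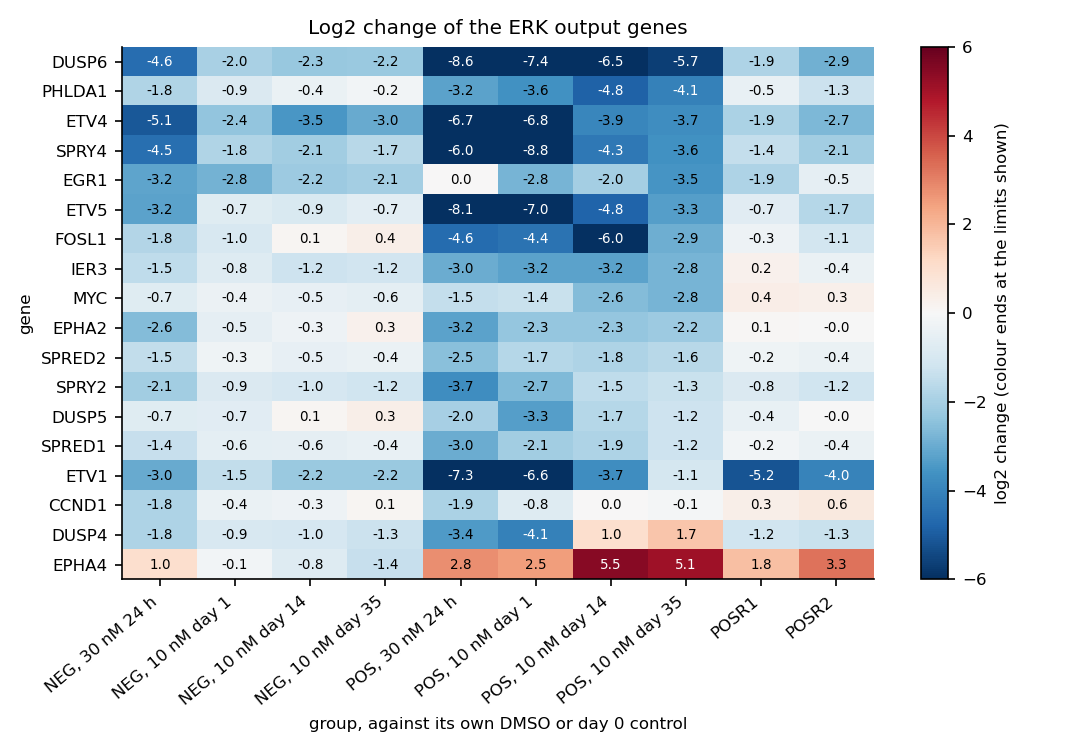
Log2 change of each of the 18 ERK output genes (y axis) against the DMSO or day 0 control of the same cells, in each treated or resistant group (x axis, 3 libraries per group). DUSP6 is negative in all 10 columns, from −1.87 in POSR1 to −8.62 in POS cells at 30 nM.

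Over 35 days of 10 nM trametinib, ERK output genes stayed low in NEG cells, while cell cycle genes fell by day 1 and rose again by day 35. DUSP6 fell from 68.6 CPM (SD 2.51) to 17.7 at day 1 and stood at 14.8 at day 35, and ETV4 fell from 33.5 to 6.5 and 4.13. ITGA2 fell from 483 CPM (SD 6.81) at day 0 to 24.0 at day 14 and 17.1 (SD 0.963) at day 35, and AREG from 90.7 to 6.26. ACTA2 rose from 4.69 to 41.8 CPM, CTGF from 249 to 1243, COL8A1 from 243 to 1032, SUSD2 from 16.9 to 118 and JPH2 from 2.58 to 32.0. At day 1, EGR1 had fallen from 73.8 to 10.3 CPM and HMGA1 from 1300 to 367, while WISP2 had risen from 5.30 to 25.1. ERK output genes fell at day 1 in 17 of 18 cases (median −0.82, adjusted p 1.04e-15) and at day 35 in 14 of 18, with 4 rising (median −0.91, adjusted p 7.73e-06). All 24 cell cycle genes fell at day 1 (median −0.51, adjusted p 1.04e-15), and at day 35 the list was no longer called (10 rose, 6 fell, median 0.10, adjusted p 0.674). Between day 1 and day 35 all 24 rose (median 0.48, adjusted p 7.47e-14) and all 22 interferon-stimulated genes fell (median −1.07, adjusted p 3.77e-14). IFIT2 fell from 108 to 24.1 CPM in that interval, OASL from 114 to 31.4 and KLHDC7B from 58.6 to 6.72. Of 14 inflammatory cytokine genes, 12 were lower at day 35 than at day 0 (median −1.48, adjusted p 4.83e-05, or 0.145 with estimated correlation). edgeR called 7408 of 14877 genes at day 1, 7848 at day 14 and 8565 at day 35, and 8652 between days 1 and 35 (n = 3 per day).

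Under the same 10 nM, POS cells raised KRT1, KRT4 and GPNMB by day 14 and COL3A1 and SPARC by day 35. At day 1, DUSP6 had fallen from 369 CPM (SD 25.0) to 2.22 (SD 0.461), ETV5 from 187 to 1.45, EREG from 823 to 20.8 and AREG from 652 to 42.6, while KRT13 had risen from 66.4 to 649, LY6D from 38.8 to 505 and FBXO32 from 37.2 to 397. At day 14, KRT1 had risen from 0.0949 to 326 CPM, KRT4 from 0.0936 to 117, S100A8 from 0.172 to 165, SPINK5 from 1.18 to 339 and GPNMB from 4.79 to 5883. CCL20 had fallen from 42.6 to 0.151 CPM, IL1A from 158 to 5.33 and VIM from 718 to 59.0. At day 35, COL3A1 had risen from 1.06 CPM (SD 0.934) to 3598 (SD 118), SPARC from 0.112 to 275, ACTA2 from 6.00 to 437, TAGLN from 9.18 to 534 and FN1 from 794 to 4890. Kinase genes PDGFRB (0.345 to 23.5) and KIT (0.0800 to 26.5) rose as well.

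The mesenchymal and epithelial junction lists both rose in POS cells between day 0 and day 35, with exceptions. CDH1 rose from 308 to 673 CPM between day 0 and day 35, while VIM stood at 374 against 718, SNAI2 at 77.2 against 142 and CDH2 at 45.5 against 70.8. Of 25 mesenchymal genes, 20 rose and 5 fell by day 35 (median 2.75, adjusted p 1.98e-05). At day 14 the list was not called: 11 rose and 9 fell, with a median of 0.31 and a test in the other direction (adjusted p 0.847). From day 1 to day 35, 21 of 25 rose (median 2.11, adjusted p 2.66e-09). Of 22 epithelial junction genes, 20 had risen at day 14 (median 1.27, adjusted p 2.21e-07) and 19 at day 35 (median 1.08, adjusted p 2.05e-05).

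ERK output and proliferation stayed low in POS cells through day 35. ERK output genes fell in 17 of 18 cases at day 1 (median −3.26, adjusted p 4.20e-13), in 15 at day 14 (median −2.46, adjusted p 2.85e-07) and in 16 at day 35 (median −2.48, adjusted p 1.14e-06). Between day 1 and day 35, 14 of the 18 rose in part (median 1.42, adjusted p 0.00292, or 0.308 with estimated correlation), and DUSP6 stood at 7.26 CPM. EPHA4 went against its list, from 2.32 CPM at day 0 to 77.7 at day 35. All 24 cell cycle genes were lower on each of the 3 days (medians −1.66, −2.43 and −2.31, adjusted p 3.25e-18, 2.27e-14 and 3.28e-14), and MKI67 stood at 47.0 CPM at day 35 against 323. Lysosome and autophagy genes were higher at day 35 in 15 of 18 cases (median 1.00, adjusted p 2.05e-05), with CTSD going from 706 to 2696 CPM. Replication-dependent histone genes rose in 7 of 8 cases (median 2.08, adjusted p 0.00144), and receptor tyrosine kinase genes in 18 of 27, with 6 falling (median 1.43, adjusted p 0.0269, or 0.116 with estimated correlation). Inflammatory cytokine genes fell in 11 of 14 cases (median −1.73, adjusted p 0.00398, or 0.116), and cholesterol synthesis genes fell after day 1 in 15 of 17 (median −0.97, adjusted p 4.66e-06). The apoptosis regulators as a list were not called at day 35 (5 rose, 6 fell, median −0.02, mean 0.27, adjusted p 0.560), although BMF rose from 3.82 to 74.0 CPM. edgeR called 10227, 11754 and 11846 of 14877 genes on days 1, 14 and 35, and 10509 between days 1 and 35 (n = 3 per day). No library of the chronic series was kept without drug past day 0, so drug and time in culture change together.

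**Figure D2:**
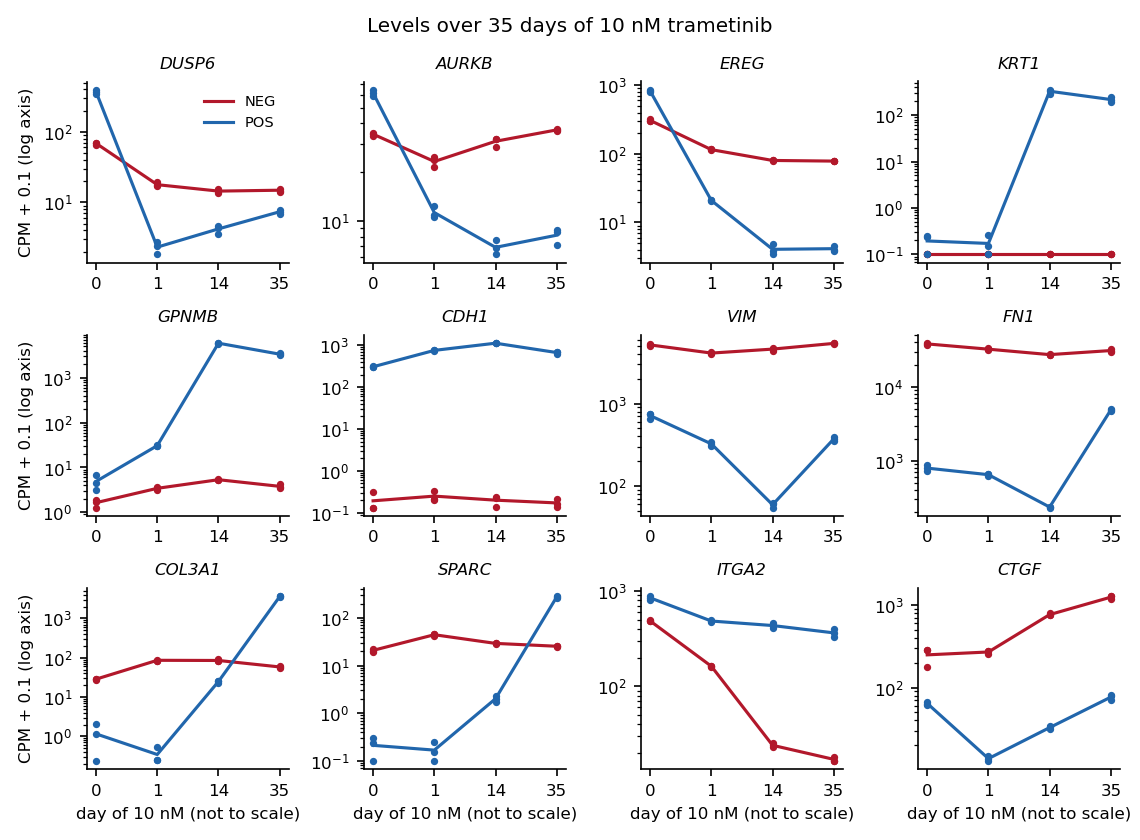
CPM plus 0.1 (log axis) of 12 genes on days 0, 1, 14 and 35 of 10 nM trametinib (spaced evenly), with 1 point per library and a line through the means of 3 libraries. COL3A1 in POS cells goes from 1.06 CPM at day 0 to 3598 at day 35.

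The POS and NEG responses differed at days 1, 14 and 35 of the chronic series. Relative to NEG cells, all 24 cell cycle genes had a lower change in POS cells on each of these days (medians −1.12, −2.34 and −2.48, adjusted p 5.17e-20, 3.51e-17 and 9.62e-18). ERK output genes had a lower change in 16, 14 and 14 of 18 cases (medians −2.53, −1.67 and −1.52, adjusted p 1.52e-13, 2.98e-05 and 2.92e-05), with ETV5 at −6.29 and DUSP6 at −5.42 on day 1. Replication-dependent histone genes had higher changes in POS cells (medians 1.31, 2.95 and 2.64 over 8 genes, adjusted p 7.93e-05, 2.98e-05 and 9.29e-05). IGFBP3 had a higher change in POS cells on day 1 (3.47), and GPNMB (8.51) and KRT15 (8.67) on day 14, when COL8A1 went the other way (−6.81). At day 35 the change of the mesenchymal list differed between the 2 cell states: 20 of 25 genes had a higher and 5 a lower change in POS cells (median 2.92, adjusted p 1.96e-07), with SPARC at 10.95 and COL3A1 at 10.73. Most genes of that list were lower in POS cells at day 0, so a higher change there goes toward the NEG level. COL14A1, which is not in that list, stood at 12.45. EREG fell further in POS cells (−5.69), and IGF2 fell in POS cells from 14.1 to 0.267 CPM and rose in NEG cells from 1038 to 1822 (−6.51). Lysosome and autophagy genes had a higher change in 15 of 18 cases (median 0.77, adjusted p 3.70e-06). edgeR called 7926, 9982 and 10613 of 14877 genes for the difference at days 1, 14 and 35 (n = 3 per group).

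**Figure D3:**
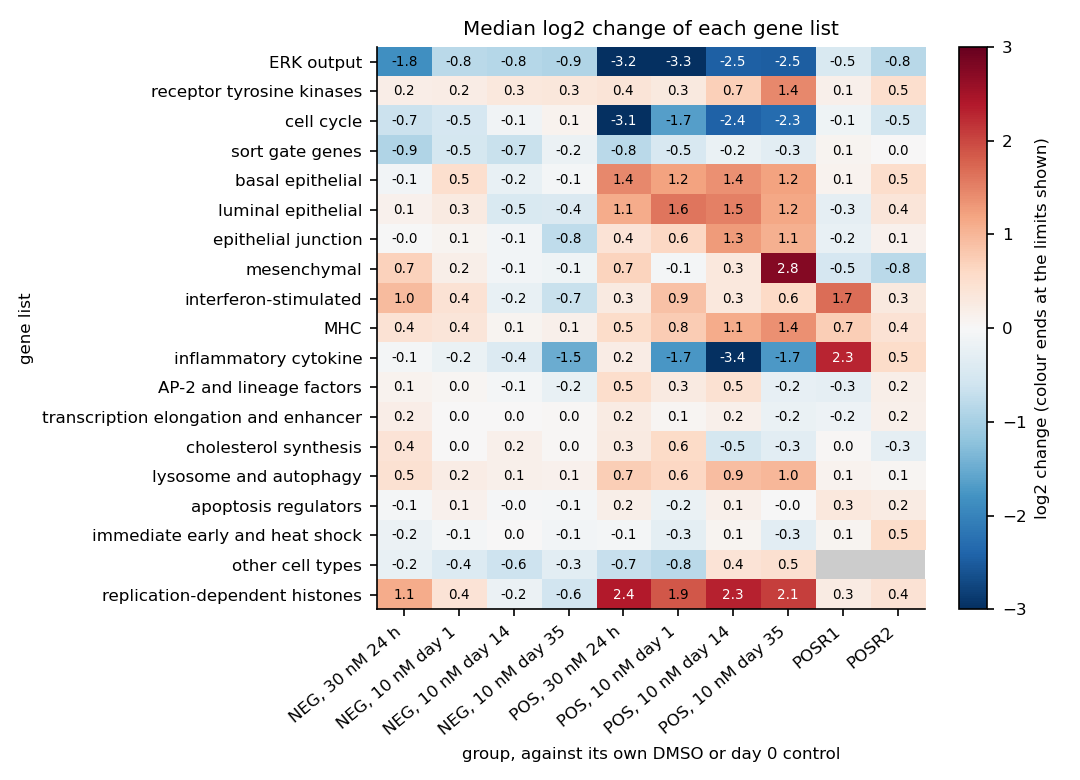
Median log2 change of each of the 19 gene lists (y axis) against the DMSO or day 0 control of the same cells, in each treated or resistant group (x axis, 3 libraries per group; grey, too few genes measured). The mesenchymal list reaches 2.75 in POS cells at day 35 and the ERK output list −3.26 in POS cells at day 1.

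Genes that set POS and NEG cells apart at baseline show the late change of the POS cells too. The 200 genes higher in NEG cells had a median change of 0.00 in POS cells at day 1 (27 rose, 26 fell, adjusted p 0.395), 0.55 at day 14 (adjusted p 0.310) and 2.14 at day 35 (121 rose, 18 fell, adjusted p 3.32e-06). These are changes from day 0, not levels. With lower bounds in place of fitted changes for genes at 0 in 1 group, the 3 medians were 0.08, 0.45 and 1.87. Of the 51 above 50 CPM in NEG cells at day 35, 15 stood in POS cells below 0.85% of that level. The 51 ranged from CXCL12 at 0% to GGT5 at 153%. The 200 genes higher in POS cells stood above day 0, with medians of 0.64, 0.76 and 0.54 on the same days (adjusted p 2.11e-10, 9.09e-08 and 0.00230), with 114 higher and 67 lower at day 35. Between day 1 and day 35, 72 of them rose and 94 fell, and the list was not called (median −0.08, adjusted p 0.132), but with 100 genes it was called lower (32 rose, 55 fell, adjusted p 0.0108). In NEG cells at day 35 the NEG-high genes moved both ways and the list was not called (75 rose, 83 fell, median −0.02, mean −0.12, adjusted p 0.511). At 30 nM for 24 h, POS-high genes rose in POS cells (194 measured, 110 rose, 19 fell, median 0.77, adjusted p 0.00433, or 0.325 with estimated correlation). For the acute groups the lists come from the day 0 libraries and for the chronic groups from the DMSO libraries, so that no list was chosen on the values it is tested on.

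**Figure D4:**
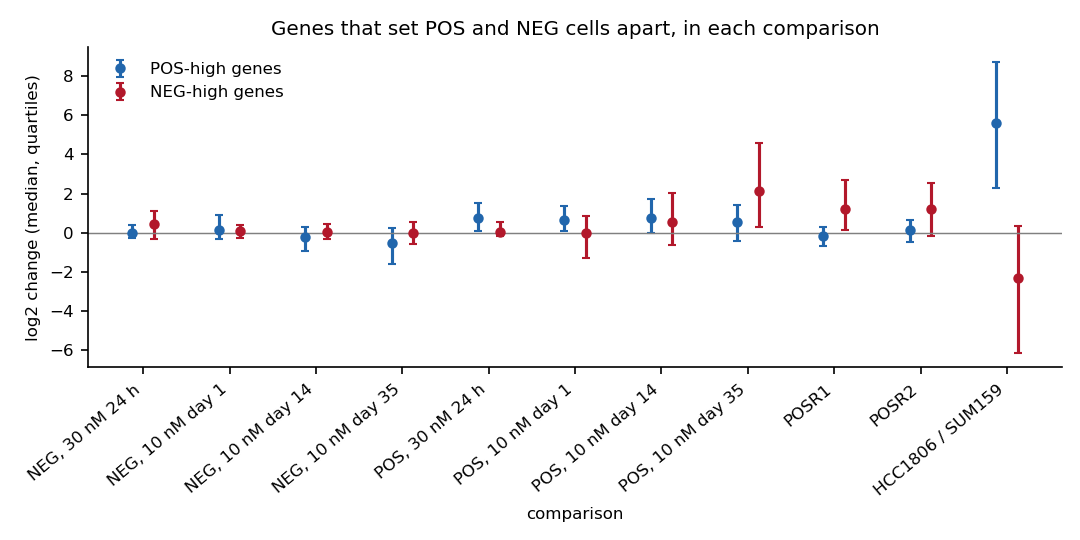
Median and quartiles (bars) of the log2 change (y axis) of the 200 genes highest in POS cells and the 200 highest in NEG cells at baseline, in each comparison (x axis). NEG-high genes reach a median of 2.14 in POS cells at day 35, by fitted changes without lower bounds.

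Both resistant POS lines carried less of several ERK output transcripts and of ITGA5 and SERPINA1 than POS cells in DMSO. DUSP6 stood at a mean signal of 1495 in POS cells, 408 in POSR1 and 202 in POSR2, and ETV4 at 437, 116 and 66.8. The integrin gene ITGA5 went from 16930 to 2372 and 2136, and the protease inhibitor gene SERPINA1 from 872 to 47.4 and 18.4. ERK output genes fell in 13 of 18 cases and rose in 5 in POSR1 (median −0.45, adjusted p 0.171), and fell in 13 and rose in 3 in POSR2 (median −0.83, adjusted p 0.00401, or 0.0656 with estimated correlation). Cell cycle genes fell in 23 of 24 cases in POSR2 (median −0.54, adjusted p 7.08e-12) and in 14 of 24, with 4 rising, in POSR1 (median −0.13, adjusted p 0.127), where MKI67 went from 6636 to 2891. Against DMSO libraries 4 to 6, the POSR1 cell cycle median was −0.42 (adjusted p 0.000445). limma called 8710 of 13127 genes in POSR1 (3836 higher, 4874 lower) and 8287 in POSR2 (4209 higher, 4078 lower, n = 3 each). At least 2-fold, 565 rose and 887 fell in POSR1, and 694 rose and 647 fell in POSR2. Between untreated POS DMSO libraries 1 to 3 and 4 to 6, limma called 5520 of 12818 genes, 65 of them at least 2-fold apart. A call alone is thus weak evidence of a change with resistance. The POSR2 balance turns with the controls and the scaling: against DMSO libraries 4 to 6, 3848 were higher and 4999 lower, and after TMM rescaling 3992 and 4319. The labels do not say whether these lines were on the drug at harvest, and both are set against the same 3 DMSO libraries.

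The 2 resistant lines otherwise diverged, with higher interferon-stimulated and inflammatory cytokine genes in POSR1. In POSR1, MX1 rose from 98.4 to 3085, IFI6 from 528 to 5887, OAS2 from 450 to 3984, IL8 from 16.5 to 400 and EPHA3 from 309 to 2221, while CA9 fell from 560 to 27.2 and FN1 from 17110 to 1787. All 22 interferon-stimulated genes rose (median 1.67, adjusted p 2.97e-16, or 0.112 with estimated correlation), and 12 of 15 inflammatory cytokine genes rose and 2 fell (median 2.28, adjusted p 3.39e-05, or 0.0514). In POSR2, KRT13 rose from 1755 to 67990, OLR1 from 12.3 to 840, IGFBP3 from 2389 to 28690, GATA3 from 46.2 to 674, FGFR2 from 453 to 2163 and KIT from 1.59 to 43.5, while VIM fell from 14220 to 2910 and EREG from 2919 to 190. Immediate early and heat shock genes rose in 9 of 12 cases in POSR2 (median 0.54, adjusted p 0.00459, or 0.211). The cytokine list was not called in POSR2 (8 rose, 4 fell, median 0.55, adjusted p 0.390), but against DMSO libraries 4 to 6 it was (1.11, adjusted p 0.00891). Set against POSR1, POSR2 had all 22 interferon-stimulated genes lower (median −1.44, adjusted p 3.22e-17, or 0.0543) and 14 of 15 cytokine genes lower (median −1.90, adjusted p 1.21e-07). Of the AP-2 and lineage factors, 11 of 13 were higher in POSR2 (median 0.68, adjusted p 2.02e-05). Genes of transcription elongation and enhancers were higher in 9 of 13 cases (median 0.20, adjusted p 0.00580, or 0.125). MX1 stood at 569 in POSR2, IFI6 at 970 and NT5E at 172 against 1500 in POSR1. limma called 7754 of 13127 genes between them, 4458 higher and 3296 lower in POSR2, and after TMM rescaling 3885 higher and 3955 lower, so this split rests on the scaling too. The test on NEG-high genes in these lines depends on the filter: 72 genes passed it (medians 1.20 and 1.19), and 191 measured without it had medians of 0.36 and 0.23.

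HCC1806 and SUM159 part along the same epithelial and mesenchymal genes, with fewer calls. Their replicates spread more and HCC1806 has 2 distinct libraries. In simulated data with that spread and those libraries, 10% of genes changed 4-fold were recovered. The fewer calls thus do not show a smaller difference between the lines. What share spread and library number each have in the fewer calls was not tested. HCC1806 carried CDH1 at 243 CPM (SD 72.0) against 0.215 (SD 0.188) in SUM159, PKP1 at 225 against 0.0145 and UCHL1 at 418 against 0.0281. SUM159 carried VIM at 3933 CPM (SD 789) against 3.28 (SD 3.19) in HCC1806 and GPR116 at 368 against 0.0561. NPTX2 was listed at 0 in both HCC1806 libraries and is at least 3205-fold lower there, taking 3 counts over the group as the floor. Of 21 epithelial junction genes, 19 were higher in HCC1806 (median 6.60, adjusted p 7.08e-12, or 0.256 with estimated correlation), and basal epithelial genes were higher in 11 of 13 cases, with 1 lower (median 4.69, adjusted p 1.67e-05, or 0.256). Mesenchymal genes were lower in 17 of 25 cases and higher in 2 (median −3.05, adjusted p 2.12e-05, or 0.541). The POS-high genes of SUM-229PE were higher in HCC1806 in 134 of 177 cases and lower in 2 (median 5.61, adjusted p 1.77e-29, or 0.0812) and the NEG-high genes lower in 81 of 169 and higher in 28 (median −2.32, adjusted p 1.07e-06, or 0.135). That test of the POS-high and NEG-high genes was added after the other results had been seen. The ERK output and cell cycle lists were not called (medians 0.34 and 0.59, adjusted p 0.485 and 0.325). edgeR called 3048 of 14096 genes, 1733 higher and 1315 lower in HCC1806 (n = 2 and 3). The count depends on single libraries: without SUM159 library 3, 5904 genes are called and the ERK output and cell cycle medians are −0.05 and 0.10. Without HCC1806 library 1 or 2 the count is 780 or 600, and without SUM159 library 1 or 2 it is 1273 or 1048.

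Sorted cells and isolated cells both lowered ERK output genes at 24 h, in 1 library per condition and without a test. ERK output genes fell by medians of 1.93 and 2.00 on the log2 scale in sorted and isolated NEG cells and of 2.75 and 2.26 in sorted and isolated POS cells. Cell cycle genes fell by 0.63 and 1.32 in NEG cells and by 1.08 and 1.83 in POS cells. Interferon-stimulated genes rose by 1.24 and 0.63 in NEG cells and 1.31 and 0.63 in POS cells, and basal epithelial genes by 0.80 and 1.27 in POS cells. Each of these 14 medians lies outside the central 95% of 10000 random lists of equal size and level. Sorted NEG cells carried more epithelial transcript than isolated ones, with CDH1 at 7.19 against 0.617 CPM in DMSO. Sorted POS cells carried less KRT5 (453 against 3271 CPM) and more FN1 (4243 against 890 CPM).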

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

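The comparisons and interaction tests in this part were planned, while the tests by other splits of the libraries were written after the counts had been seen. The POS response to trametinib differed from the NEG response by a test of the difference itself. At 30 nM for 24 h, limma called 8870 genes, with medians of −1.47 for the ERK output list (adjusted p 0.00131, or 0.504 with estimated correlation) and −2.67 for the cell cycle list. Single genes were ETV5 (−4.88), DUSP6 (−4.02), H19 (−3.63), LMNB1 (−3.49), EGR1 (3.22), IGFBP3 (3.75) and KRT13 (3.97), and the POS-high genes had a median of 0.83 (adjusted p 0.000104, or 0.153 with estimated correlation). Of 100 drawn splits within cell type, 1, the real one, gave as many genes, and the highest other gave 7280 with the POS labels intact. These splits also break the treatment effects of each cell type, so they do not decide whether the difference between cell types is chance.

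In the chronic series the same interaction gave 7926 genes at day 1, 9982 at day 14 and 10613 at day 35 by edgeR. At day 1 the medians were −2.53 for ERK output, −1.12 for cell cycle and 1.31 for replication-dependent histones, with ETV5 at −6.29, DUSP6 at −5.42 and IGFBP3 at 3.47. At day 14 they were −1.67, −2.34 and 2.95, with GPNMB at 8.51, KRT15 at 8.67, COL8A1 at −6.81 and the POS-high genes at 1.21 (adjusted p 0.0314, or 0.177 with estimated correlation). At day 35 they were −1.52, −2.48 and 2.64, with the mesenchymal list at 2.92, lysosome and autophagy at 0.77 and the NEG-high genes at 2.47, and with COL14A1 at 12.45, SPARC at 10.95, COL3A1 at 10.73, IGF2 at −6.51 and EREG at −5.69. In fits of the 4 groups of each day, 1 of 50 drawn splits, the real one, gave as many genes on each day, with the same limit. The real values were 7461, 9538 and 10193 and the highest others 6938, 8813 and 8286, each with the POS labels intact.

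Time points differed within each cell type. Between day 1 and day 35, NEG cells had 8652 genes called, with the cell cycle list at 0.48, the interferon-stimulated list at −1.07, KLHDC7B at −3.12, IFIT2 at −2.16, OASL at −1.86 and the POS-high genes at −0.88 (adjusted p 0.0127, or 0.104 with estimated correlation). POS cells had 10509, with the mesenchymal list at 2.11, cholesterol synthesis at −0.97, ERK output at 1.42 (adjusted p 0.00292, or 0.308 with estimated correlation) and the NEG-high genes at 2.35. POSR2 differed from POSR1 in 7754 genes, with interferon-stimulated genes at −1.44 (0.0543 with estimated correlation), inflammatory cytokine genes at −1.90, AP-2 and lineage factors at 0.68, transcription elongation and enhancer genes at 0.20 (0.125 with estimated correlation) and the POS-high genes at 0.28. MX1 (−2.45), IFI6 (−2.60) and NT5E (−3.12) were lower in POSR2.

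Single libraries stood apart in the 2 groups of 6, NEG and POS DMSO, in 7 of 46 checks where chance gives about 2.3 (1 in 20 groups). Each group joins 2 sets of unlike depth, so that rate is only a guide. NEG DMSO library 3 had a mean Spearman correlation with the others of 0.976 (nearest other 0.985), a cell cycle mean log2(value + 1) of 11.5 (11.8), a lysosome and autophagy mean of 9.81 (10.2) and an other cell types mean of 1.43 (1.93). It is also the shallowest library of its group, at an implied 7.05 M counts against 13.4 to 31.8 M in the others. POS DMSO library 1 had a mesenchymal mean of 7.21 (7.08) and an AP-2 and lineage factors mean of 8.28 (8.18), and POS DMSO library 6 an other cell types mean of 1.53 (1.38).

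In comparisons of 3 libraries against 3, only 10 splits exist, too few for a share under 0.05, and 1, the real one, gave as many genes in each. Every other split mixes the 2 real groups, which turns their difference into spread within groups. Low counts in those splits follow from this, so they do not decide whether the calls are chance. The real count and the highest other were 10482 and 1 for acute NEG, 11133 and 1 for acute POS, 11943 and 0 for POS against NEG in DMSO and 11878 and 0 at day 0. They were 7408, 7848, 8565 and 8652, each with 0, for NEG cells at days 1, 14 and 35 and between days 1 and 35. For POS cells they were 10227 and 1, 11754 and 0, 11846 and 1, and 10509 and 0. They were 8710 and 0 for POSR1, 8287 and 0 for POSR2, and 7754 and 2 between these lines.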

How the results depend on the processing

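TMM rescaling, the repeated HCC1806 values, the block in the list tests and estimated correlation for the POS-high and NEG-high lists were chosen after the values were seen. The number of genes called stayed within 1.5 times its value under every alternative run for 18 of the 20 comparisons. The acute difference (8870) gave 4820 with all 6 DMSO libraries and 4699 with DMSO libraries 1 to 3, and 8464 to 8660 with 1 library left out. HCC1806 against SUM159 (3048) gave 5077 by DESeq2, 5307 with the repeated HCC1806 values counted, and 600 to 5904 with 1 library left out. The cause was not tested. With the correlation estimated from the data, the list tests gave 59 calls in place of 156, and the POS-high and NEG-high lists 13 in place of 20. With 100 or 400 genes per list, the latter gave 22 or 20.

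Library numbers are shared between groups, but same-numbered libraries did not deviate together: 0 of 18 acute and 0 of 84 chronic pairs correlated above 0.1, and 1 of 9 resistant and 1 of 2 line pairs. With a replicate block, HCC1806 against SUM159 gave 4894 genes in place of 3048. SUM159 library 3 has no HCC1806 library of its number in that fit, since HCC1806 library 3 was counted once. The block thus sets SUM159 library 3 apart, and this count cannot tell pairing by number from leaving that library out (5904 genes). The list tests gave 161 calls with the block. No other count moved by over 1.5 times under the block (acute NEG 10472, acute POS 11128).

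Genes named in the text kept direction and call under every alternative run. Of the lists named, the cell cycle list in POSR1 (−0.42) and the cytokine list in POSR2 (1.11) became called with DMSO libraries 4 to 6, and the interferon-stimulated list in baseline DMSO lost its call with DMSO libraries 1 to 3 (−0.19) and with all 6 (−0.36). Over all lists, the MHC list in the acute difference went from 0.22 to −0.004 with DMSO libraries 1 to 3. With DMSO libraries 1 to 3, 22 of 30 list calls held, with all 6 DMSO libraries 35 of 43, and with 1 library left out 1103 of 1116. TMM rescaling moved the median of all genes in acute NEG from 0.10 to 0.01 and in the acute difference from −0.07 to 0.08. In the sorted and isolated cells, 98 of 160 medians lay outside the random range, and 97 or 99 under other settings. DESeq2 and RLE factors were not run on the signal files, which are not counts, nor pseudocounts on the expected counts. The lines' libraries spread beyond counting error: chi-square per gene was 334 and 315 for SUM159 library 3 against libraries 1 and 2, and 6 between those.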

Other observations

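The tests of SUM159 library 3, of HCC1806 library 1 against 2, of DMSO libraries 1 to 3 against 4 to 6, of levels in the sorted libraries, of NEG RNA and of drug-free libraries were chosen after the results were seen. Further genes changed in POS cells by day 35 of 10 nM trametinib. SPRR1A rose from 0.0321 to 66.2 CPM and S100A8 from 0.172 to 334, ELF3 from 23.0 to 379 and TFAP2C from 12.2 to 54.1. CD74 rose from 0.576 to 35.2 CPM and BCL2 from 0.375 to 4.6. The receptor genes FGFR3 (12.9 to 134 CPM) and FGFR4 (54.7 to 3.31) moved in opposite directions, and the ligand gene HBEGF fell from 163 to 3.97. In POSR2, EGFR rose from a signal of 7180 to 10910 and DDR1 from 12740 to 24550.

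The 2 distinct HCC1806 libraries differ in KRT13, KRT4, RGS4 and CCND2, chosen after their values were seen. KRT13 stood at 442 CPM in library 1 and 3.1 in library 2, KRT4 at 316 and 3.81, RGS4 at 0.0379 and 71.2, and CCND2 at 65.7 and 741. Between DMSO libraries 1 to 3 and 4 to 6, limma called 49 of 12850 genes in NEG cells. In POS cells it called 5520 of 12818, 65 of them at least 2-fold apart. The lower NEG count does not show closer sets, since the lowest Spearman correlation between sets was 0.975 in NEG and 0.9877 in POS cells. NEG DMSO library 3, at an implied 7.05 M counts, is among them, and its effect on the count was not tested. In POS cells, a call alone can thus reflect a difference between sets of untreated libraries. In the sorted libraries in DMSO, POS-high genes stood in NEG cells at a median of 2.68% of their POS level (0.537% in isolated cells), and NEG-high genes in POS cells at 4.55% of their NEG level (1.06% in isolated cells).

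NEG-high genes rise in POS cells between day 0 and day 35, by a median of 2.14, or 1.87 with lower bounds for genes at 0 in 1 group. NEG cells or their RNA in the POS day 35 libraries would need 8.5% of NEG RNA for the median riser, and 15 of 51 abundant NEG-high genes lie below 0.85%, CXCL12 at 0 and PDGFRA at 0.0456% among them, which argues against it. For a shift of scaling or of genes near the floor, 0 of 10000 random lists of equal mean level reach 2.14, the highest reaches 1.52 and their median is 0.74. This argues against a shift of scaling shared by genes of equal mean level. The lists were matched on the mean over all POS days, not on day 0, so they do not decide whether genes near the floor at day 0 contribute. Whether 35 days of 10 nM trametinib rather than 35 days in culture is the cause cannot be told apart, since 0 POS libraries were kept without drug to day 14 or 35. A gain of NEG-type genes by POS cells may remain as a hypothesis.

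SUM159 library 3 stands apart from SUM159 libraries 1 and 2. MEK-inhibited cells under a DMSO label may explain it: 17 of 18 ERK output genes are lower (median −1.91), with DUSP6 at 0.428 CPM against 10.1 and 11.9, and 24 of 24 cell cycle genes (median −3.37). Its changes correlate across 13167 genes, which are not independent, with those of acute NEG (0.636) and acute POS (0.646). RNA of HCC1806, NEG or POS cells in the library is argued against by low median shares of abundant genes that libraries 1 and 2 lack. These medians were 0.19% for HCC1806 (82 genes), 0.216% for NEG (45) and 0.176% for POS cells (79). Slow growth of SUM159 cells without the drug stays open, with 0 libraries to test it.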
